A study of Mus musculus with 3 samples.

How the data were processed

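RNA was measured in single EpCAM-positive cells of 3 mouse pancreatic tumours, 1 library per tumour. Per the labels' protocols, tumours were minced, digested with collagenase, treated with red blood cell lysis buffer and sorted; up to 16000 cells were loaded per 10x Genomics well, and libraries were sequenced on a HiSeq4000 with a target of 50000 reads per cell. The labels name both a Version 1 and a Version 3 3' kit, and the one that applies to each step was not settled here. The deposited values are whole-number UMI counts per gene and barcode, with no normalization, made by Cell Ranger 3.0.2 per the file headers (Cell Ranger 3 and mm10 per the submitters' processing notes, which also name Seurat 3.1). Each table lists 31053 genes and all 6794880 possible barcodes, so no cell calling had been applied. The gene annotation that the authors used is not given in the sources used here; coordinates are those of GENCODE annotation for the same build (mm10), matched by gene identifier for all 256 genes looked up.

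Cells were barcodes with 1000 or more UMIs, 500 or more genes and at most 20% mitochondrial UMIs. The same barcodes recurred across the 3 libraries: all 1877 barcodes with 1000 or more UMIs in library 1 also had 10 or more in library 2, where chance gives 18.4. A barcode was therefore kept as a cell of a library only if 60% or more of its UMIs over the 3 libraries lay there. This home-library filter was added after the data were examined, departs from the plan written beforehand, and removed 122, 258 and 28 barcodes (7.86%, 50.5% and 0.989%) that passed the other filters, so tumour 2 lost the largest part. It left 1431, 253 and 2804 cells, and shares, list levels, free RNA, correlations, cycling shares, gene and list tests and leading genes were also computed without it. Doublets were called per tumour with the scrublet method of scanpy 1.11.5, which marked 4, 3 and 0 cells; these were removed. So few calls in this many cells say little about how many doublets were present, and removing the 5% of cells with the highest scores was added as an alternative.

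Counts were scaled to 10000 per cell and log-transformed. The 2000 most variable genes entered clustering, without mitochondrial, ribosomal protein, haemoglobin, Xist and Y-linked genes and without members of the gene lists that were not also cell type markers. Clustering used 30 principal components, 15 neighbours and the Leiden method at resolution 0.5 (leidenalg 0.10.2, scikit-learn 1.9.0, Python 3.11.15), with no batch integration, and gave 12 clusters, 9 of them with 50 or more cells. The 14 marker lists were fixed before the data were examined; the rule that applies them was set after the clusters were seen. A cluster of 10 or more cells was named for the list with the most members at 20 CPM or more and 2-fold or more above the other cells, if at least 3 members met this, if no other list had more members among the 10 leading genes, and if fewer than 3 of these were Gm42418, AY036118, Gm26917 or Lars2. Clusters of 1 class were joined: the acinar-like class holds clusters led by histone genes with Clps and Ctrb1 (795 cells), by trypsinogens (58 cells) and by Rsad2, Fosb and Ifit1 (78 cells with a median of 16063 UMIs), and the ductal-like class clusters led by Tff1 (1059 cells) and by Chil3 and Onecut2 (45 cells with a median of 14910 UMIs). Cluster 3 was taken into the tests, after the clusters were seen, as the unnamed cluster with the highest Epcam level among those of 100 or more cells not led by ribosomal RNA locus genes. Amy2b, Loricrin, Irag2, Btnl8 and Fam3d of the lists had no entry under those names in the count tables.

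Levels are summed UMIs scaled to a total of 1000000 (CPM), computed here, with exact Poisson intervals kept beside them; shares have exact Clopper-Pearson 95% intervals. Both cover counting error only, and a count of 0 is read against a floor of 3 counts. Gene tests used raw UMIs summed per tumour and class where a class had 50 or more cells in a tumour, which gave 9 sums of 201513 to 2611970 UMIs. edgeR 4.0.16 (R 4.3.3) fitted all sums together with filterByExpr, TMM factors and the tumour as a block, on 8582 genes with 3 residual degrees of freedom and a common biological coefficient of variation of 0.117, and glmQLFTest gave p-values with Benjamini-Hochberg adjustment at 0.05. Clustering genes were left out of all counts of genes, leaving 7646, since they defined the classes. The 13 gene lists, also fixed beforehand, were tested with camera (limma 3.58.1) at a preset correlation of 0.01. An estimated correlation and fry served as checks. With an estimated correlation camera also reads its statistic at the 3 residual degrees of freedom, so few lists can pass whatever their correlation. Fry tests whether a list's genes move, on balance, one way and does not compare the list with other genes. The classes of a tumour come from the same animal, so the tumour pairs them; deviations from the class means correlated at 0.187, 0.0877 and 0.330 over 8268 genes in tumours 1, 2 and 3. With the tumour as a block, p-values set the differences between classes against their spread from tumour to tumour. edgeR moderates that spread with information shared across genes. With 3 residual degrees of freedom, very small p-values rest largely on this sharing and not on the tumours alone. The p-values of cluster 3 rest on 2 tumours and share each gene's estimate of spread with the other classes. Classes were found from the same UMIs that were then tested, which count splitting addresses as an alternative. The test was tried on simulated counts for ductal-like against acinar-like cells: of 200 changed genes 180 passed the filter on low counts beside 7237 unchanged ones. Counting those filtered out as missed, it recovered 65% of genes changed by 1 and 82% of those changed by 2 on the log2 scale, and called 4 of the unchanged genes.

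Named genes followed a rule written beforehand: the 5 most abundant genes of each of the acinar, ductal, squamous and cornified lists; Myc, Msi2, Msi1, Epcam, Ptprc and Mki67; per pair of classes the 10 genes higher and 10 lower with the largest fold among non-clustering genes with adjusted p of 0.05 or less, a log2 change of 1 or more and the same sign in every tumour; the 4 members of each list with the smallest p; and per tumour the 10 genes with the largest log2 ratio to the mean of the other tumours after adding 5 CPM. Some genes that this rule names are not reported here and are left out of the counts of alternative values of named genes. Genes with 0 UMIs in a class are given as a bound against 3 counts, and those with 1 to 3 UMIs as a ratio with its counting interval. Free RNA was taken from barcodes with 10 to 100 UMIs that met the same home-library share. Cell cycle shares and correlations across cells used cells thinned to 1000 UMIs, which left out 0 cells. Alternatives were other limits on UMIs, genes and mitochondrial share, other clustering settings, DESeq2 1.42.0, no filter on low counts, no tumour block, each tumour left out, doublets kept and count splitting, all fixed beforehand, and the home-library, denominator, ribosomal RNA, doublet score, high-UMI, histone cluster, AY036118 cluster and list member settings added afterwards. The cause of the home-library pattern, and the subtype of each tumour, were not analysed further than stated.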

Results

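Single cells were profiled from 3 mouse pancreatic tumours. Each tumour grew in an immunodeficient NSG mouse after tdTomato-positive epithelial cells were transplanted into its pancreas. The donors combined the Msi2-Myc model with the R26-LSL-tdTomato reporter, and their cells were taken as pre-cancer cells 5 weeks after tamoxifen, which switches on MYC and the red reporter through CreER of the Msi2 line. At the end stage EpCAM-positive cells, that is epithelial cells, were sorted and put through droplet-based 3' RNA sequencing with unique molecular identifiers (UMIs). The stated question was whether one pool of transcriptionally uncommitted pre-cancer cells gives rise to several tumour subtypes. The series title names ASCP, PDAC and ACC tumours, but all 3 samples carry the same labels apart from their titles, so they form 1 group of 3 tumours. No tumour was assigned a subtype and no test was made between tumours. The count tables held 11502184, 9737397 and 16521484 UMIs for tumours 1, 2 and 3. After all filters 1427, 250 and 2804 cells were analysed. Before doublet calling, the median kept cell had 1621, 1333 and 1605.5 UMIs and 740, 734 and 680 genes. Values of tumour 2 therefore rest on the fewest cells.

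Acinar-like cells, named from digestive enzyme genes such as Ctrb1 and Clps, were present in every tumour. They made up 20.7% of cells in tumour 1 (exact binomial 95% interval 18.6 to 22.9), 22.8% in tumour 2 (17.7 to 28.5) and 20.6% in tumour 3 (19.2 to 22.2), with a mean of 21.4% ± 1.24 (SD, n = 3). Ductal-like cells, led by the gastric-type secretory genes Tff1 and Lgals4, made up 39.9% (37.3 to 42.5), 49.6% (43.2 to 56.0) and 14.7% (13.4 to 16.0), a mean of 34.7% ± 18.03 (SD, n = 3). Squamous-like cells, led by the keratins Krt14, Krt5, Krt15, Krt6a and Krt17, were found as 74 of 2804 cells in tumour 3 (2.64%, 2.08 to 3.30), against 2 of 1427 in tumour 1 (0.140%, 0.0170 to 0.505) and 2 of 250 in tumour 2 (0.8%, 0.0970 to 2.86). Each tumour thus held acinar-like and ductal-like cells, and the squamous-like interval of tumour 2 overlapped that of tumour 3. The acinar-like cells were not alike in all tumours. Their acinar list was at 9209 CPM in tumour 2, against 26774 and 28297 CPM in tumours 1 and 3. The trypsinogen-led cluster of this class held 22, 0 and 36 cells of tumours 1, 2 and 3. An unnamed epithelial cluster, called cluster 3 here, held 7.92%, 3.6% and 4.07% of cells. Olfr1369-ps1, which also led the genes of tumour 1, was its first leading gene. Tm4sf1, Ankrd1, Msln, Plat, Ly6a, F3 and Lgals3 were among its other leading genes. The ductal list matched cluster 3 best, with 5 members 2-fold or more above the other cells. Only the mesothelial marker Msln among the leading genes kept the cluster from being named ductal-like. Its ductal list stood at 9940 and 10932 CPM in tumours 1 and 3, against 15384 and 18187 CPM in ductal-like cells. Intervals cover counting error only, and the EpCAM gate and the minimum of 1000 UMIs can set all of these shares. With every barcode kept, without the requirement that a barcode belong mainly to 1 library, the acinar-like shares were 23.8%, 31.6% and 21.2%, the ductal-like shares 40.8%, 41.5% and 15.1%, and the squamous-like counts 11, 21 and 74. Of these, 25 of the 32 squamous-like barcodes of libraries 1 and 2 then had most of their UMIs in library 3.

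**Figure D1:**
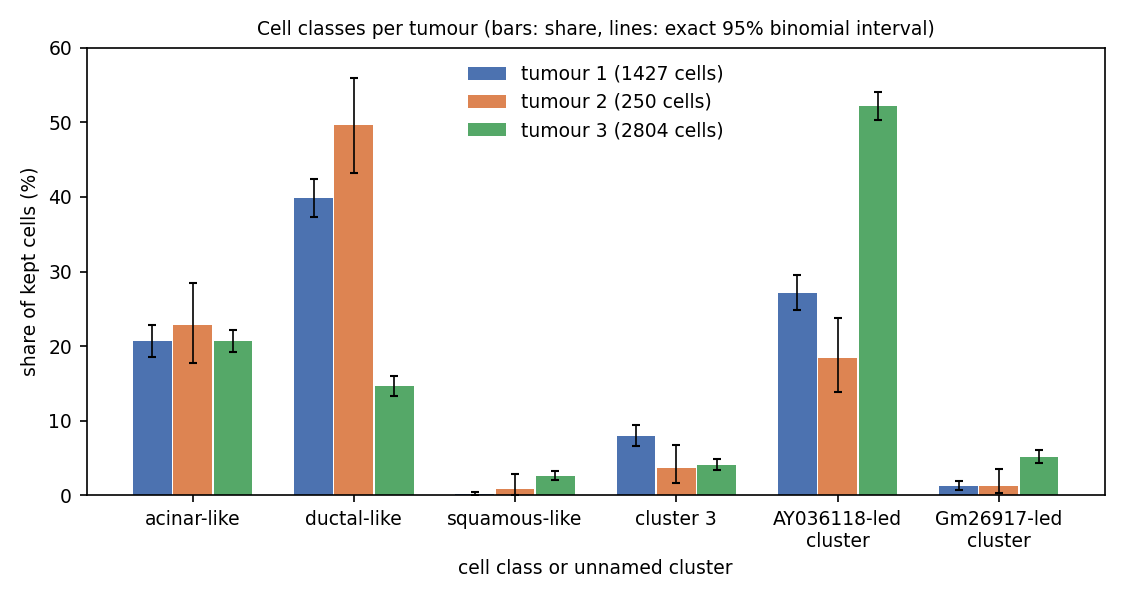
Share of kept cells (y axis, %) in each cell class or unnamed cluster (x axis) for tumours 1, 2 and 3, with bars for the share and lines for the exact 95% binomial interval. The acinar-like bars stand at 20.7%, 22.8% and 20.6%, while the ductal-like bars run from 14.7% in tumour 3 to 49.6% in tumour 2.

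The remaining cells fell into clusters left without a name. A cluster led by AY036118 and Gm42418, genes of the ribosomal RNA locus, took 27.2% of cells in tumour 1 (24.9 to 29.6), 18.4% in tumour 2 (13.8 to 23.8) and 52.2% in tumour 3 (50.3 to 54.0). It also had the acinar genes Amy1 and Pnlip among its leading genes, and a rule set after the clusters were seen kept it unnamed because 3 of its 10 leading genes were ribosomal RNA locus genes or Lars2. Counted as acinar-like, an alternative chosen after the data were seen, it would bring the acinar-like shares to 47.9%, 41.2% and 72.8%, so the close shares given above depend on this rule. Over the 3 named classes alone, acinar-like cells made up 34.1%, 31.1% and 54.4% and ductal-like cells 65.7%, 67.8% and 38.6%, so the size of this cluster sets how the shares of tumour 3 read. A cluster led by Gm26917 held 1.26%, 1.2% and 5.17% of cells, and the rest held 2.94%, 3.6% and 0.642%, mostly in a cluster of 66 cells led by histone genes. Of 4488 cells, 7 were called doublets and removed.

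Summed over all kept cells, the acinar list was highest in tumour 3, at 16531 CPM (UMIs scaled to a total of 1000000), against 8316 in tumour 1 and 4993 in tumour 2, a mean of 9946 ± 5939 CPM (SD, n = 3). The ductal list varied less, at 9765, 8719 and 7393 CPM (8626 ± 1189). The squamous list stood at 479, 853 and 1475 CPM (936 ± 503) and the cornified list, genes of the outer layers of skin-like epithelium, at 489, 369 and 482 CPM (447 ± 67.3). Ctrb1, a precursor of the digestive protease chymotrypsin (chromosome 8, 111686519 to 111691010, mm10), was the most abundant acinar gene at 3942 ± 2262 CPM, followed by the lipase-related Pnliprp1, the trypsinogen Prss2, the colipase Clps and the carboxypeptidase Cpa1. Of the ductal genes, the epithelial keratin Krt19 (chromosome 11, 100140810 to 100148665) reached 2079 ± 278 CPM and the trefoil peptide genes Tff1 and Tff2 2050.3 ± 750.4 and 1551 ± 274 CPM, with Lgals4 and the transcription factor gene Onecut2 next. Ly6d, Sfn and the desmosome gene Dsp led the squamous list, and the basal keratin Krt5 (chromosome 15, 101707070 to 101712898) was at 25.7, 102 and 215 CPM. Cornified transcripts came mainly from Sprr2a3 and Sprr1a, precursors of the cornified envelope, with Il1rn, Ivl and Dmkn below them. Trypsinogen genes are near-identical copies, so the split of UMIs among them is uncertain.

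Free RNA, measured in barcodes with 10 to 100 UMIs, held the acinar list at 9894, 7925 and 19700.3 CPM and the ductal list at 6667, 8216 and 5977 CPM. The cells before doublet removal had the acinar list at 8320.02, 4950.4 and 16531 CPM and the ductal list at 9761, 8751 and 7393 CPM. Markers of cells that the EpCAM gate should exclude stayed low in the cells kept by the home-library filter. The fibroblast list averaged 13.1 CPM, the endothelial list 18.6, the myeloid list 55.3, the lymphoid list 1.41, the erythroid list 1.24, the Schwann cell list 30.4 and the hepatocyte list 13.0. With every barcode kept, a cluster led by Ttr and haemoglobin genes held 10, 30 and 7 barcodes of libraries 1, 2 and 3. It had the erythroid list at 20387 CPM, so the low levels do not show the gate alone. The mesothelial list averaged 40.5 CPM, with Msln among the leading genes of cluster 3, and among epithelial lists the tuft cell list averaged 58.6 CPM and the endocrine list 0.705 CPM.

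Squamous-like cells were numerous enough to sum only in tumour 3, so they entered no test. In those 74 cells Krt5 stood at 3656 CPM, against 41.1 CPM in the ductal-like and 6.13 CPM in the acinar-like cells of the same tumour, and Krt14 (chromosome 11, 100203162 to 100207548) at 2943 CPM against 15.5 and 6.89. Trp63, the master transcription factor of squamous epithelium, was at 191 CPM, from 65 UMIs, against 3.36 CPM in ductal-like cells. These keratins define the class. The cornified list, which was not used to name it, was at 1049 CPM in squamous-like cells, against 855 in ductal-like cells and 1465 in cluster 3 of that tumour. Epcam was at 486 CPM in squamous-like cells and 919.97 in ductal-like cells.

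**Figure D2:**
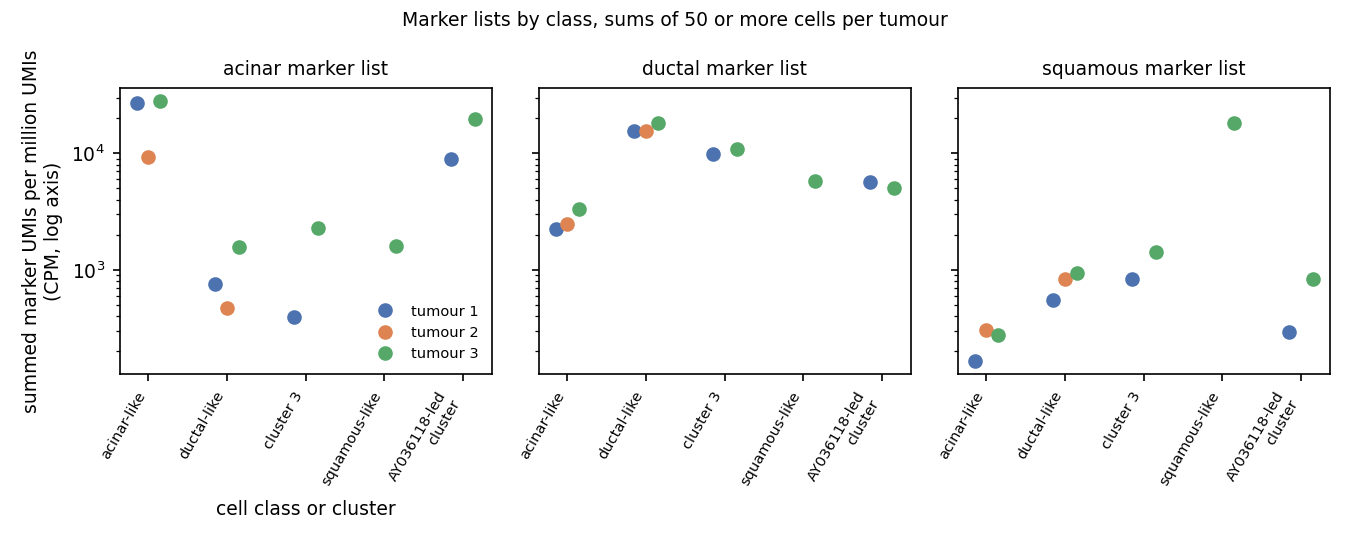
Summed UMIs of the acinar, ductal and squamous marker lists in CPM (y axis, log scale) in each class or cluster (x axis), 1 point per tumour where the class held 50 or more cells. The squamous list reached 18314 CPM in the squamous-like cells of tumour 3 and stayed at 1421 CPM or below in every other class shown.

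Whether the programs sit in the same cells was read from rank correlations across cells after each cell was thinned to 1000 UMIs. Acinar and ductal list UMIs ran against each other within every tumour, with Spearman's rho of -0.674, -0.566 and -0.392 (mean -0.544). Cells with 10 or more UMIs of both lists numbered 25, 6 and 111, against 145, 18.1 and 382 expected if the lists were independent. Acinar and squamous UMIs had a mean rho of -0.250, and ductal and squamous UMIs of 0.237. Without the 3 most abundant free RNA genes of each list, these means were -0.504 for acinar and ductal, -0.0459 for acinar and squamous and 0.0531 for ductal and squamous UMIs, so only the first pair kept its size. Cells are not replicates, and no p-value was computed across them.

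Ductal-like and acinar-like cells were then compared within tumours, on raw UMIs summed per class and tumour, to ask how these cell states differ. The S phase, G2/M and MYC target lists were lower and the classical PDAC list higher in ductal-like cells by camera with a preset correlation. None of these list calls held with an estimated correlation (adjusted p = 0.109, 0.320, 0.109 and 0.177). Fry, which does not compare a list with other genes, called all 4 (adjusted p = 0.00382, 0.0216, 0.00169 and 0.00325). The nuclear RNA Malat1, a clustering gene, moved with them, at 3787, 6610.0 and 8248 CPM in ductal-like against 2148, 2572 and 3670.4 CPM in acinar-like cells of tumours 1, 2 and 3. Nasp, a histone chaperone of S phase (chromosome 4, 116601052 to 116627941), stood at 99.4 CPM in ductal-like and 370.0 CPM in acinar-like cells, a log2 difference of -1.69 ± 0.16 (SE, adjusted p = 5.74e-14, lower in 3 of 3 tumours). Anxa10, an annexin of gastric-type epithelium and also a ductal marker (chromosome 8, 62057042 to 62123150), stood at 336 against 29.0 CPM (log2 3.74 ± 0.20). As a marker it helped to name the class, so no p is read for it. Msi2, an RNA-binding protein gene of stem and progenitor cells whose CreER line marks the donors (chromosome 11, 88339382 to 88718513), was at 125 ± 23.3 CPM in ductal-like and 51.3 ± 10.9 CPM in acinar-like cells (SD over tumours, log2 1.12 ± 0.19, adjusted p = 2.97e-06). Across 7646 genes that had not been used for clustering, 1301 were higher and 1274 lower in ductal-like cells (edgeR's quasi-likelihood test with the tumour as a block and Benjamini-Hochberg adjustment).

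Of the 42 S phase genes, 31 were lower in ductal-like cells, 0 were higher and 11 did not pass (35 lower when adjusted over the list alone). The largest acinar-like cluster, 795 of 931 cells, had 4 histone genes among its 10 leading genes, so this difference can partly follow from how the class was formed. With the unnamed histone-led cluster counted as ductal-like, an alternative chosen after the data were seen, the S phase list's camera adjusted p was 1.30e-11, and 0.0712 with an estimated correlation. Rrm2, a subunit of ribonucleotide reductase, fell by 1.56 and the replication licensing inhibitor Gmnn by 1.51 on the log2 scale. Of 49 measured G2/M genes 31 were lower, 1 was higher and 17 did not pass (35 and 1 adjusted over the list alone), with Cks2 falling by 1.34 and the topoisomerase Top2a by 1.49. Of 30 MYC target genes 29 were lower and 1 did not pass (29 adjusted over the list alone): the spermidine synthase gene Srm fell by 1.57, the nucleolar gene Nolc1 fell by 1.11 and Npm1 fell by 0.95. By camera with a preset correlation of 0.01 the adjusted p was 4.41e-12 for S phase, 7.91e-09 for G2/M and 2.61e-10 for MYC targets, and adjusted p = 0.109, 0.320 and 0.109 with an estimated correlation. Of 19 ER stress genes 11 were lower, 1 was higher and 7 did not pass (11 and 2 adjusted over the list alone), among them Sel1l of ER-associated degradation, which fell by 2.23, and the chaperone gene Hspa5, which fell by 0.91 (camera adjusted p = 0.00626, and adjusted p = 0.320 with an estimated correlation). In the hypoxia and glycolysis list 11 of 20 genes were lower and 1 higher (11 and 1 adjusted over the list alone), with Pdk1 falling by 1.05 and Eno1 by 0.67 (camera adjusted p = 0.0393, and adjusted p = 0.648 with an estimated correlation). All 6 classical PDAC genes left after removing clustering genes were higher (6 adjusted over the list alone). Besides Anxa10, Krt20 rose by 4.87 ± 0.39, the brush border myosin Myo1a by 4.44 ± 0.38 and Vsig2 by 3.78 ± 0.30 (camera adjusted p = 2.40e-06, 3.93e-05 without Anxa10, and 0.177 with an estimated correlation).

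**Figure D3:**
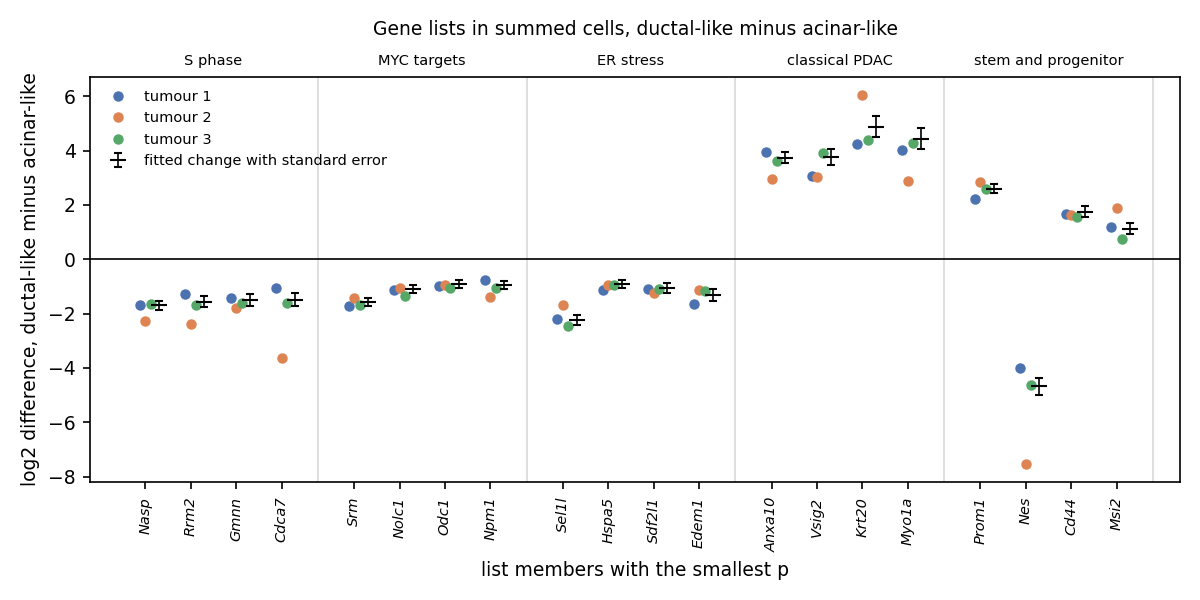
Log2 difference, ductal-like minus acinar-like (y axis), of the 4 members with the smallest p in 5 gene lists (x axis), with a coloured point per tumour and a black bar for the fitted change and its standard error. Nasp lies at -1.69 and Anxa10 at 3.74, and the stem and progenitor genes split, with Prom1 at 2.59 and Nes at -4.67.

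Of the 7 lists that did not pass, 6 held genes called in both directions. Of 9 stem and progenitor genes 5 were higher and 2 lower (5 and 3 adjusted over the list alone), with Prom1, a membrane glycoprotein of progenitor cells, at 509 against 86.2 CPM (log2 2.59 ± 0.17) and Nes, an intermediate filament gene, at 2.75 against 128 CPM (log2 -4.67 ± 0.31). The list's adjusted p was 0.335, with a median above 0 and a mean below 0. Of 7 MHC class I genes 3 were higher and 1 lower (3 and 1 adjusted over the list alone): H2-D1 rose by 0.79 while the immunoproteasome gene Psmb10 fell by 2.14 (list adjusted p = 0.293). Of 11 interferon genes 2 were higher and 4 lower (2 and 4 adjusted over the list alone), with Bst2 falling by 1.21 and an adjusted p of 0.979, its median and mean below 0 and its test upward. The immediate early list had 3 of 18 higher, among them Klf4 (log2 1.13), and 3 lower (3 and 3 adjusted over the list alone), its median below 0, its mean above 0 and an adjusted p of 0.912. Of 6 mesenchymal transition genes 2 were higher, among them Mmp14 (log2 2.31), and 1 lower, with the same counts adjusted over the list alone and an adjusted p of 0.761. The basal-like PDAC list had 3 of 9 higher, such as Anxa8 (log2 2.56), and 1 lower (5 and 1 adjusted over the list alone; adjusted p = 0.101, but 0.0165 with clustering genes among its members, an alternative chosen after the data were seen, and 0.214 with these and an estimated correlation). The list of beta oxidation and OXPHOS had 6 of 18 higher, such as Cox5a (log2 0.58), and 0 lower (6 and 0 adjusted over the list alone; adjusted p = 0.0865).

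Beyond the lists, 7 of the 10 genes picked as highest in ductal-like cells had 0 UMIs in acinar-like cells. Naip1, an inflammasome sensor gene, had 79 UMIs in ductal-like and 0 in acinar-like cells, at least 29.8-fold higher against a floor of 3 counts over the group. Kctd12b, Adam28, Gpr27, Jakmip1, Gm17025 and Cers3 likewise had 61, 48, 41, 41, 33 and 24 UMIs in ductal-like and 0 in acinar-like cells, from at least 23.0-fold for Kctd12b to at least 9.06-fold for Cers3. DESeq2 did not call Kctd12b and Gm17025 (adjusted p = 0.365 and 0.423). Sytl2, a vesicle transport gene, had 100 UMIs against 1 (113-fold, counting interval 19.9 to 4515), Mcpt2 70 against 1 and the fucosyltransferase Fut9 69 against 1. In acinar-like cells Cckar, the cholecystokinin receptor that drives enzyme secretion (chromosome 5, 53697776 to 53707705), was at 121 ± 32.6 CPM against 2.93 ± 3.93 (log2 -4.91 ± 0.32, adjusted p = 6.23e-21). The sulfotransferase Chst2 was at 142 ± 40.1 against 2.71 ± 3.55 (log2 -5.22 ± 0.32, adjusted p = 6.41e-22). The receptor tyrosine kinase gene Kit (chromosome 5, 75574916 to 75656722) had 126 UMIs in acinar-like cells and 1 in ductal-like cells (111-fold, counting interval 19.6 to 4431), and Kng2, Klk1b3, St6galnac4 and Rims4 had 120, 87, 82 and 48 against 1. Matn4, Pld4 and the antiviral gene Rsad2 completed the set with 303, 149 and 270 UMIs against 7, 3 and 5. Tumour 3 gave most of these UMIs, 255 of 270 for Rsad2, 116 of 120 for Kng2 and 130 of 149 for Pld4.

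Of the genes fixed for naming, Epcam was at 839 ± 134 CPM in ductal-like and 562 ± 198 in acinar-like cells (log2 0.75 ± 0.15, adjusted p = 4.74e-05). Mki67, a proliferation marker, was at 207 ± 69.0 against 296 ± 78.7 (log2 -0.47 ± 0.16, adjusted p = 0.0149), a call lost with DESeq2 (adjusted p = 0.246), with no tumour block (0.255) and without tumour 3 (log2 -0.18, adjusted p = 0.663). Myc was at 34.7 ± 3.04 against 45.0 ± 8.15 CPM and did not pass (adjusted p = 0.258), and UMIs of the mouse gene and of the transgene were not told apart. Msi1 had 1 UMI in ductal-like and 0 in acinar-like cells, and the blood cell gene Ptprc 2 and 1. DESeq2 called 560 genes higher and 427 lower, the fit with no tumour block 803 and 641, and a test on UMIs not used for clustering 732 and 647 of 4398 genes tested. Without tumour 3 the counts were 481 and 366, without tumour 1 797 and 874, and with every barcode kept 1630 and 1646. Clusters of high UMI counts held 41.0% of the acinar-like and 25.1% of the ductal-like UMIs, and without them, an alternative chosen after the data were seen, the counts were 1185 and 1127.

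Cells with many cell cycle UMIs were also more frequent among acinar-like cells. At 10 or more S or G2/M UMIs after thinning to 1000 UMIs, a threshold set after the overall level was seen, 35.6%, 49.1% and 29.2% of acinar-like cells but 11.6%, 13.7% and 9.002% of ductal-like cells were counted. The mean difference was -26.5 percentage points ± 7.92 (SD, n = 3), lower in 3 of 3 tumours, with an exact two-sided sign-flip permutation p of 0.25, the smallest that 3 tumours allow. In cluster 3 the shares were 13.3% in tumour 1 and 11.4% in tumour 3, and in the squamous-like cells of tumour 3 9.46%. Without thinning the difference was -42.0 points and with the histone-led cluster counted as ductal-like -24.7 points, and free RNA enters these counts per cell.

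Cluster 3 was set against ductal-like cells in tumours 1 and 3, where both held 50 or more cells. Genes of hypoxia and glycolysis were higher in cluster 3: Ndrg1, a hypoxia-induced gene (chromosome 15, 66929318 to 66969640), stood at 367 against 41.5 CPM (log2 3.27 ± 0.22, adjusted p = 7.90e-19). The vasodilator peptide gene Adm stood at 215 against 21.9 CPM (log2 3.27 ± 0.29), the glucose transporter gene Slc2a1 at 163 against 33.6 CPM (log2 2.36 ± 0.25) and Bnip3 at 145 against 27.5 CPM (log2 2.60 ± 0.28), each higher in both tumours. Of the 20 genes of that list 16 were higher and 4 did not pass (18 adjusted over the list alone; camera adjusted p = 1.71e-12, and adjusted p = 0.260 with an estimated correlation). Of 6 mesenchymal transition genes 3 were higher and 3 did not pass (4 adjusted over the list alone; camera adjusted p = 0.00160, and adjusted p = 0.260 with an estimated correlation). Of these, the fibronectin gene Fn1 had 28 UMIs against 2 (50.3-fold, counting interval 12.7 to 435). Of 19 ER stress genes Herpud1, Sdf2l1 and Hyou1 were lower (3 adjusted over the list alone), falling by 1.02, 0.93 and 1.08, though Sdf2l1 was at log2 0.20 on UMIs not used for clustering (camera adjusted p = 0.000164, and adjusted p = 0.260 with an estimated correlation). Of 42 S phase genes Hells and Cdc6 were lower, falling by 0.96 and 2.59 (0 adjusted over the list alone; camera adjusted p = 0.00160, and adjusted p = 0.260 with an estimated correlation).

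**Figure D4:**
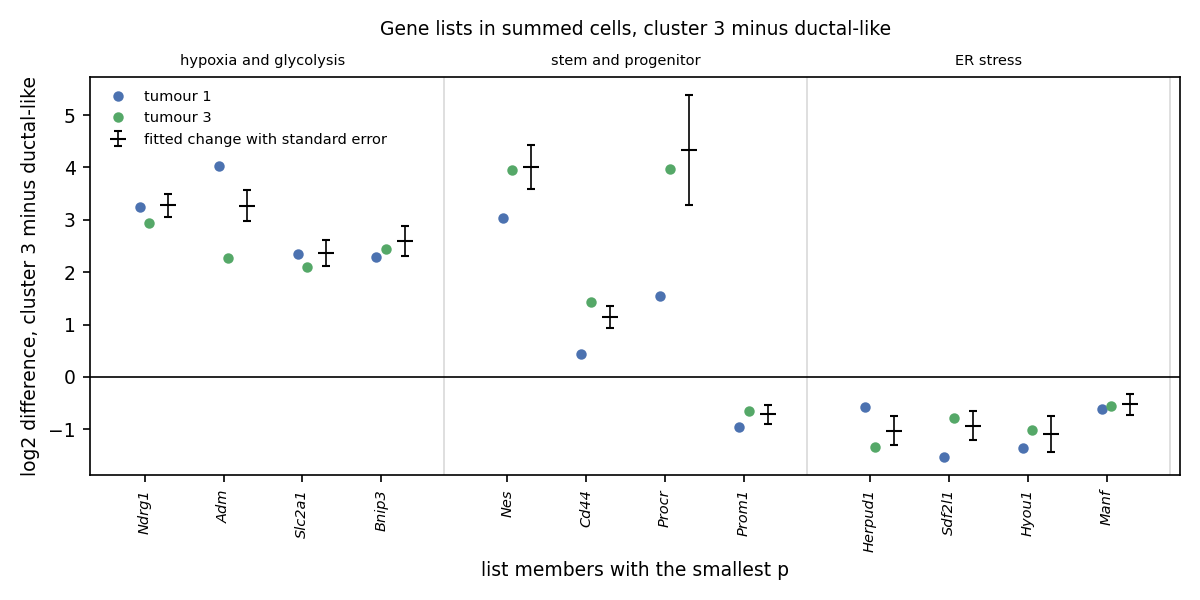
Log2 difference, cluster 3 minus ductal-like (y axis), of the 4 members with the smallest p in 3 gene lists (x axis), with points for tumours 1 and 3 and a black bar for the fitted change and its standard error. Ndrg1 lies at 3.27, while Herpud1 lies at -1.02.

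Other lists did not pass in this comparison on members that were not clustering genes. Values with all tested members, clustering genes included, come from an alternative chosen after the data were seen. Of 9 stem and progenitor genes Nes (log2 4.004 ± 0.42), Cd44 (log2 1.15 ± 0.22) and Procr were higher and Prom1 lower (log2 -0.71 ± 0.19), the same counts as adjusted over the list alone, with an adjusted p of 0.605, a median below 0 and a mean above 0. The basal-like PDAC list had 3 of 9 higher (3 adjusted over the list alone), Slc2a1, the growth factor gene Areg (log2 1.94) and Itga3 (log2 1.66), with an adjusted p of 0.0529, but 0.00152 and higher with all tested members, and 0.235 with these and an estimated correlation. In the immediate early list Ier3 (log2 2.10) and Dusp1 (log2 0.93) were higher and Fosb lower (log2 -1.59), against 5 and 3 adjusted over the list alone and an adjusted p of 0.495. Of 49 G2/M genes 2 were higher, among them Anln (log2 1.37), and 3 lower, Smc4, Cbx5 and Mki67 (3 and 3 adjusted over the list alone; adjusted p = 0.922, its median and mean of opposite sign). Of 11 interferon genes Bst2 was higher (log2 1.18; 2 adjusted over the list alone; adjusted p = 0.354), and of 6 classical PDAC genes Myo1a was lower (log2 -1.92; 1 higher and 2 lower adjusted over the list alone; adjusted p = 0.920, but 0.00163 and lower with all tested members, and 0.278 with these and an estimated correlation). MYC targets, MHC class I and the list of beta oxidation and OXPHOS had 0 genes past the threshold over all genes (adjusted p = 0.511, 0.509 and 0.0809), and 0, 0 and 3, all lower, adjusted over the list alone.

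A few markers of other cell types had more UMIs per total in cluster 3, read without a test. The mesothelial list stood at 260 and 431 CPM in tumours 1 and 3 against 28.6 and 74.0 in ductal-like cells, all of it from Msln, since the other 5 members had 0 UMIs in both. The myeloid list stood at 102 and 168 CPM against 63.5 and 95.6, mostly from Cd14 and Cd68, with 0 UMIs of C1qa, C1qb, C1qc, Adgre1 and Tyrobp in both. The nuclear RNA Malat1 was at 10688 and 14208 CPM against 3787 and 8248. Over all genes not used for clustering, 248 were higher and 160 lower in cluster 3. The cell adhesion gene Mcam had 13 UMIs in cluster 3 and 1 in ductal-like cells (46.7-fold, counting interval 7.01 to 1983) and the collagen gene Col27a1 25 and 2 (44.9-fold, 11.2 to 391). Map1b, Cited1, Pxdc1, Procr, Glrp1 and St6galnac4 had 23, 17, 15, 15, 14 and 6 UMIs against 3, 3, 2, 2, 2 and 1. Of the lower genes, Mocs1, Kctd12b and Arhgef38 had 85, 60 and 35 UMIs in ductal-like cells and 0 in cluster 3, at least 7.89-fold, 5.57-fold and 3.25-fold lower. Sult1b1, a sulfotransferase, was at 4.65 against 46.8 CPM (log2 -3.23 ± 0.57, adjusted p = 2.86e-05), and Ccl28, Tox3, Msh3, 5330417C22Rik, Rab27a and Pigb had 1 to 3 UMIs against 53, 48, 51, 59, 83 and 58. Of the 10 lower genes DESeq2 called Mocs1 alone, with 8 others at an adjusted p of 0.0914 (Sult1b1) to 0.539 and none given for Kctd12b. Of the 10 higher genes it called 6, with Pxdc1, Procr and St6galnac4 at an adjusted p of 0.0723, 0.122 and 0.199 and none given for Cited1. Procr had 1 UMI in each class in tumour 1, so tumour 3 carries it. Mki67 was at 98.9 against 179 CPM (log2 -0.76 ± 0.23, adjusted p = 0.0260), a call lost under 6 alternatives, such as DESeq2 (adjusted p = 0.434; range over the 6 0.137 to 0.589), whereas Epcam (862 against 802 CPM), Msi2 (91.4 against 113) and Myc (34.5 against 34.7) did not pass. DESeq2 called 70 and 8 genes, the fit with no tumour block 110 and 29, and a test on UMIs not used for clustering 90 and 54. With every barcode kept the counts were 363 and 305, with clustering genes included 374 and 238.

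Against acinar-like cells of tumours 1 and 3, the S phase, G2/M, MYC target and ER stress lists were lower in cluster 3 and the hypoxia, mesenchymal and PDAC lists higher by camera with a preset correlation. None of these list calls held with an estimated correlation (adjusted p from 0.117 to 0.399). Fry, which does not compare a list with other genes, called all of them but hypoxia and glycolysis (adjusted p = 0.0619). Il1a, an inflammatory cytokine gene (chromosome 2, 129299610 to 129309972), had 77 UMIs in cluster 3 and 0 in acinar-like cells, at least 105-fold higher. Areg rose to 389.5 from 17.7 CPM (log2 4.32 ± 0.28, adjusted p = 1.90e-20) and Cd44, a hyaluronan receptor, to 175 from 26.8 CPM (log2 2.90 ± 0.24). Nr5a2, a transcription factor of acinar cells and one of the acinar markers, had 121 UMIs in acinar-like cells and 0 in cluster 3, at least 9.85-fold lower. In tumours 1 and 3 Malat1 was at 10688 and 14208 CPM in cluster 3 against 2148 and 3670.4 in acinar-like cells. Gm42418 was at 39118 and 22033 against 15278 and 10124.5 CPM, and the mesothelial list at 260 and 431 against 5.58 and 6.89 CPM. In all 1038 genes were higher and 845 lower, against 512 and 216 with DESeq2, 745 and 442 with no tumour block, 351 and 195 on UMIs not used for clustering and 1236 and 1235 with every barcode kept.

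Among the lists, 31 of 42 S phase, 25 of 49 G2/M, 22 of 30 MYC target and 12 of 19 ER stress genes were lower in cluster 3 and 0 were higher (31, 29, 25 and 14 adjusted over the list alone; camera adjusted p = 5.12e-14, 4.82e-07, 2.88e-07 and 3.80e-06). With an estimated correlation these lists had an adjusted p = 0.117, 0.270, 0.117 and 0.117. Nasp fell by 1.83, Mki67 by 1.22, Srm by 2.02 and Sel1l by 3.02. All 6 classical PDAC genes, 11 of 20 hypoxia and glycolysis genes, 4 of 6 mesenchymal transition genes and 4 of 9 basal-like PDAC genes were higher and 0 lower (6, 11, 4 and 4 higher, and 1 hypoxia gene lower, adjusted over the list alone; camera adjusted p = 5.02e-06, 0.000664, 0.00512 and 0.00219). Examples were Krt20 (log2 5.03), Adm (log2 4.37) and Mmp14 (log2 3.26). With an estimated correlation the adjusted p was 0.117, 0.399, 0.122 and 0.117. The stem and progenitor list had 4 of 9 higher and 0 lower (6 and 2 adjusted over the list alone; adjusted p = 0.148), among them Prom1 (log2 1.88), Sox4 (log2 0.88) and Msi2 (log2 0.88, but -0.078 on UMIs not used for clustering). MHC class I had 4 of 7 higher and 1 lower, Psmb10 (log2 -2.66), and the immediate early list 5 of 18 higher and 3 lower, among them Fosb (log2 -2.03), with adjusted p of 0.109 and 0.350 (4 and 1, and 5 and 5, adjusted over the list alone). The interferon list had Irf7 higher (log2 2.74) and Rsad2 lower (log2 -3.40) of 11, and the list of beta oxidation and OXPHOS Acadl and Cox4i1 higher and Hadhb lower of 18, with adjusted p of 0.350 and 0.830 and the same counts adjusted over the list alone. The median and mean of the immediate early and interferon lists had opposite signs.

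The other genes picked for this pair by size of change were near absent from one side. Col27a1, Pxdc1, Adam28 and Cers3 had 25, 15, 13 and 6 UMIs in cluster 3 and 0 in acinar-like cells (at least 34.1-fold to at least 8.19-fold higher). Nbl1, Wincr1, Gpr137b, the Wnt ligand gene Wnt7b and Tspan2 had 34, 27, 25, 22 and 21 against 1 or 2. On the lower side Anpep, Cd6, Klk1b3, Kirrel2, Gm15441, Cmpk2, Pipox and Cwf19l1 had 87, 84, 83, 72, 60, 57, 53 and 43 UMIs in acinar-like cells and 0 in cluster 3 (at least 7.08-fold to at least 3.50-fold lower). Cd6 and Cmpk2 had 1 UMI each in tumour 1, so tumour 3 carries them, and DESeq2 called neither (adjusted p = 0.839 and 0.358), nor Kirrel2 and Gm15441 (0.107 and 0.0515), and gave none for Pipox. Cckar had 451 against 1 (110.1-fold, counting interval 19.7 to 4359). Epcam was at 862 against 466 CPM (log2 0.99 ± 0.18), but cluster 3 was chosen for its Epcam level, so no p is read. Myc, at 34.5 against 47.7 CPM, did not pass (adjusted p = 0.690).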

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

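All tests in this part were chosen after the results were seen. Barcodes that belonged mainly to none of the 3 libraries, and entered no comparison, carried transcripts that were near absent from the analysed cells. In library 2 the 144 of these barcodes with 1500 or more UMIs over the libraries held the erythroid list at 104096 CPM, the transthyretin gene Ttr at 13713.4 CPM and the endothelial list at 6334 CPM, where the limit that a count of 0 allows is 21.0 CPM at 142561 UMIs. There were no control samples to set them against. In the 22260 with 100 or more but under 1000 UMIs, the erythroid list stood at 13658 CPM and Ttr at 30.1 CPM in that library. Over all libraries, Apoe, Cldn5 and Flt1 in those 144 were at 4509.8, 2972 and 2502 CPM, against 12.5, 4.86 and 4.31 in barcodes of that size with a home library. Haemoglobin genes are near-identical copies, so only their sum is read.

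The first pattern weighed is the sharing of barcodes. Chance use of the same barcode by separate droplets is argued against, because shared barcodes were at least 62.9 times as many as chance gives in all 6 ordered pairs of libraries. Reads of one library's molecules counted in another are a candidate explanation: a median of 99.4% or more of the genes under a barcode were also found under it in its home library in every pair, against a 95th percentile of 66.7% to 78.0% for another barcode. Barcodes at home in libraries 1, 2 and 3 had medians of 75.3%, 77.7% and 80.1% of their UMIs there. The step at which this arose, in sequencing or in the assignment of reads to libraries, was not tested, and no biological explanation was tested.

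The second pattern is the squamous-like barcodes of libraries 1 and 2 when every barcode is kept. Squamous-like cells of those tumours themselves are argued against for most of them, since 4 of 32 (12.5%, exact 95% interval 3.51 to 29.0) had their home in their own library and 25 had it in library 3. The few that remain, 2 in each of tumours 1 and 2 in the report, are not excluded as cells of their own tumours. The same barcode can occur in both libraries, so 1 cell may enter the 32 more than once and the interval may be too narrow.

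The third pattern is the barcodes with no home, which were 22999 of 42542 barcodes with 100 or more UMIs (54.1%). Red blood cells of these 3 tumours are argued against, because barcodes at home in a library held at most 0.00728% of the erythroid level of those with no home at 1500 or more UMIs. At 100 or more but under 1000 UMIs they held at most 90.9 CPM against 13658 CPM or more. Among barcodes with 1000 or more UMIs over the libraries, 739 with no home divided their UMIs at medians of 32.2%, 49.1% and 19.0% over libraries 1, 2 and 3. RNA from a further library that is not among these 3 may be their source, which stays open, since no value here tests it and the EpCAM gate and red cell lysis would remove such cells from these tumours.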

How the results depend on the processing

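The alternatives on the home-library filter, the denominator of named classes, the ribosomal RNA locus, doublet scores, high-UMI clusters, the histone-led and AY036118-led clusters and the members of gene lists were chosen after seeing the data; the others were fixed before the data were examined. Where a value changed and no reason is given, the cause was not tested.

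The mean acinar-like share of 21.4% was 26.3% at a minimum of 2000 UMIs, 18.6% at 200 genes, 19.99% at a mitochondrial limit of 10%, 25.5% with no home-library filter, 19.6% at a home share of 50%, 18.9% at resolution 1.0, 34.1% with a class given per cell and 54.0% with the AY036118-led cluster counted as acinar-like. Over the named classes alone it was 39.9%, the ductal-like share 57.4% instead of 34.7% and the squamous-like share 2.76% instead of 1.19%, by the smaller denominator. The squamous-like share was 3.25% at 2000 UMIs, 2.98% with each tumour clustered on its own and 19.1% per cell. The ductal list rose from 8626 to 10057 CPM when ribosomal RNA locus and mitochondrial genes left the total, and ductal free RNA was 4024 instead of 6953 CPM with no home-library filter.

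The mean correlation of -0.250 between acinar and squamous UMIs was -0.333 at 2000 UMIs, which left out 1002, 197 and 1981 cells, and -0.0459 without the 3 most abundant free RNA genes of each list, where that of ductal and squamous UMIs was 0.0531 instead of 0.237. The cycling difference of -26.5 points was -42.0 without thinning. The median log2 ratio of genes leading tumour 2, 1.89, was 2.52 and 0.91 with 1 and 20 CPM added, 0.061 in ductal-like cells alone and 1.12 with no home-library filter. For tumour 3, 2.55 became 3.14, 1.65, 1.05 and 1.33 in the same order, and for tumour 1 no alternative moved it beyond its spread.

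For ductal-like against acinar-like cells, the 1301 higher and 1274 lower genes were 560 and 427 with DESeq2, 803 and 641 with no tumour block and 732 and 647 with count splitting, which tested fewer genes (4398). Leaving out 1 tumour gave 481 to 1339 higher and 366 to 1308 lower genes. The lowest counts came without tumour 3, where fewer genes (5340) and samples were tested. For cluster 3 against ductal-like cells (248 and 160) the counts were 70 and 8 with DESeq2, 110 and 29 with no tumour block, 90 and 54 with count splitting, 374 higher with clustering genes counted and 305 lower with no home-library filter. For cluster 3 against acinar-like cells (1038 and 845) they were 512 and 216 with DESeq2, 442 lower with no tumour block and 351 and 195 with count splitting. Of the 408 and 1883 genes called for cluster 3 against ductal-like and acinar-like cells, DESeq2 called 78 and 721 in the same direction. Count splitting called 93 and 470 of them, with 109 and 605 not tested and 4 and 22 in the opposite direction. Of the 2575 genes called between ductal-like and acinar-like cells, count splitting called 1253 in the same direction, with 913 not tested. Of these 2575, DESeq2 called 960, the fit with no block 1444 and the fit with no home-library filter 2498 in the same direction. The tumour block, with correlations within tumours of 0.0877 to 0.330, thus changed these counts, and without it the lists called numbered 6, 4 and 8 as in the report. Cluster 3 could not be tested without tumour 1 or 3, since 1 tumour would remain.

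With an estimated correlation 0 lists were called in each comparison, instead of 6, 4 and 8, also with all tested members or with the histone-led cluster counted as ductal-like. Fry called 7 lists for ductal-like and 7 for cluster 3 against acinar-like cells. Both sets held S phase, G2/M, MYC targets, ER stress and classical PDAC, but not hypoxia and glycolysis. Fry does not compare a list with other genes. For cluster 3 against ductal-like cells fry called 1 list, mesenchymal transition, and camera with no home-library filter called 7. With count splitting Sdf2l1 reversed between cluster 3 and ductal-like cells (log2 0.20, from -0.93) and Msi2 between cluster 3 and acinar-like cells (log2 -0.078, from 0.88). With no filter on low counts the median log2 change over all genes was -0.12 in both cluster 3 comparisons.

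Of 2786 alternative values of named genes, 2530 kept direction and side of the threshold, 197 lost their call, 53 gained one, 2 reversed and 4 uncalled ones changed sign. Of 454 for lists, 356 kept both, 63 lost and 14 gained a call, 0 reversed and 21 uncalled ones changed direction. Of 216 values for single tumours, 99 moved beyond their counting interval. Depth limits tumour 2 most, where a class with 0 of 250 cells could still hold 1.2% of them, against 0.210% and 0.107% in tumours 1 and 3; its acinar-like and ductal-like sums held 201757 and 201513 UMIs.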

Other observations

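Tests of mitochondrial share, of Xist and of Jun in this part were chosen after the results were seen, and the other tests before. Genes leading single tumours were listed without a test, since each tumour is 1 animal. In tumour 3 the chitinase-like genes Chil4 and Chil3 and the keratins Krt15, Krt14 and Krt17 stood above the mean of the other tumours by log2 3.54, 3.05, 2.82, 2.76 and 2.42, and Chil4 was at 227 CPM against 24.5 and 5.54. Serpini2, Cldn10, the trypsinogen Gm10334, Rsad2 and Kng2 followed, with log2 ratios of 2.68, 2.33, 2.25, 2.12 and 2.10. Tumour 1 was led by Olfr1369-ps1 (log2 2.83, 81.4 CPM against 5.54 and 8.83) and the transcription factor gene Zic5 (log2 2.46, 74 UMIs against 0 and 3), then Mtus2, Cldn18, Ttr, Gm47283, Ripply3, Rpl13a-ps1 and Macrod1. Gm47283 lies on chromosome Y in the annotation used here, but had 1114 UMIs in tumour 3 as well. In tumour 2 Gm8797 led (log2 3.42), followed by the haptoglobin gene Hp (log2 2.19), Gm26809, Dqx1, the fibrinogen genes Fgb and Fga, Ptges, Gem, Loxl2 and A330069E16Rik, all but Gm8797 from 31 UMIs or fewer. The 74 squamous-like cells gave 1030 of 1323, 999 of 1239 and 349 of 566 UMIs of Krt15, Krt14 and Krt17 in tumour 3. As given above, the median ratios for tumours 2 and 3 were smaller in ductal-like cells alone.

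Sex-linked genes also separated the tumours. Xist had 1, 0 and 4786 UMIs in tumours 1, 2 and 3, while Ddx3y, Eif2s3y, Uty and Kdm5d together had 225, 47 and 0. Whether these transcripts belong to the donor or the host of each transplant is not given in the sources used here.

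The cluster led by histone genes, 66 cells, had the ductal list at 11290 CPM, and 17 of its 40 cells in tumour 1 (42.5%) had 10 or more cell cycle UMIs. Clusters with many UMIs per cell weighed more in the sums than in cells: the acinar-like one led by Rsad2 and Fosb held 78 of 931 cells but 41.0% of UMIs, and the ductal-like one led by Chil3 45 of 1104 cells but 25.1%. For ductal-like against acinar-like cells, the 6 sums can be divided into 3 and 3 in 10 ways, too few for a share under 0.05. Fitted on these sums alone with the tumour as a block, the real division gave 2615 genes and the highest other 0. Every other division mixes the classes, so their difference adds to the spread and low counts follow in advance. The contrast therefore decides nothing.

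The AY036118-led cluster was the most numerous group of tumour 3. Broken cells that kept their mitochondria are argued against, because its mitochondrial share was 1.33%, 0.725% and 0.991%, at most 1.33% where the acinar-like and ductal-like classes had 4.36% or more. Droplets with free RNA and no cell may account for it: acinar against ductal UMIs varied over its barcodes 1.69 and 2.18 times as much as draws from 1 pool give in tumours 1 and 3, and 2.20 times in tumour 2, against 6.10 to 27.0 times in the named classes. Of the bounds set beforehand, below 1.5 for free RNA was met in neither of tumours 1 and 3 and above 2 against it in tumour 3 alone, so this stays open. The comparison with the named classes is limited, since such a ratio grows with UMIs per barcode and these classes pool several clusters. The cluster's median UMIs were lower than theirs in tumours 1 and 3 (1456 against 2383 and 2132 in tumour 3) but higher in tumour 2. Barcodes with 10 to 100 UMIs, which may hold debris as well as free RNA, had Gm42418 at 268113, 208058 and 179307 CPM, nearer to the cluster's 332967, 251641 and 253811 CPM than to the 10124.5 to 23423 CPM of the acinar-like and ductal-like classes, but mitochondrial shares of 3.33%, 4.61% and 3.87%, above those of the cluster.

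The Gm26917-led cluster, 18, 3 and 145 cells, had Myc at 1138, 790 and 530 CPM (47, 8 and 180 UMIs), against 45.1, 45.2 and 41.5 CPM in the other cells of tumours 1, 2 and 3, with Jun at 6781, 3455 and 3577 CPM. A state of tumour 3 alone is argued against by tumour 1, where Jun, not a clustering gene, was 24.1 times its level in the other cells (95% interval 21.0 to 27.6), while the ratio of 25.2 for Myc (17.7 to 35.4) decides nothing, since Myc was a clustering gene. Nuclei without cytoplasm are argued against in tumour 3 alone, by Xist at most 0.435 times its level in the acinar-like and ductal-like classes, with Malat1 at 0.950 times that of acinar-like cells. In tumours 1 and 2 they stay open, with Malat1 at 4384 and 3752 CPM against 2148 and 2572 in acinar-like and 3787 and 6610.0 in ductal-like cells. A general immediate early response may contribute: without Jun, that list in tumour 3 was 1.28 times its level in acinar-like cells, under the bound of 1.5 set beforehand, and 1.73 times that in ductal-like cells. The lower of these ratios was 5.43 in tumour 1 and 1.49 in tumour 2, so a bound on tumour 3 alone was too narrow and this stays open. Members of the list differed in direction. Fos was lower in the cluster, at 48.4, 0 and 206 CPM in tumours 1, 2 and 3. In acinar-like cells Fos was at 268, 362 and 913 CPM and in ductal-like cells at 332, 432 and 617 CPM. Ier2 and Atf3 were above both classes in tumours 1 and 3. Ribosomal RNA locus genes and Lars2 together took 28.1%, 24.1% and 26.6% of the cluster's UMIs. UMIs of the mouse Myc gene and of the transgene were not told apart.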
